A study of Homo sapiens with 6 samples.

How the data were processed

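Circular RNAs (circRNAs) were measured by sequencing total RNA of MIA PaCa-2 cells, an established human line from a pancreatic ductal adenocarcinoma. Per the labels' protocols, cells were moved to medium without glucose or to high-glucose medium, both with 10% fetal bovine serum, and were harvested after 3 h, in 3 independent experiments per group. RNA was extracted with a mirVana kit and libraries were made by Illumina protocols, per the labels. The series text calls the treatment low glucose and the control normal glucose. The groups are named here after the culture-condition label of each sample, which matches the protocol. The 6 libraries form 2 groups of 3, high glucose and no glucose, and the replicate numbers come from the sample titles.

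The authors deposited 1 table of 33016 circRNAs with RPM values of back-splice junction reads, relative to all reads of the library, beside circBase names where given, GRCh38 positions, strand and a class. The aligner, the circRNA caller, its annotation and its filters are not given in the sources used here. Each value was a whole multiple of 1 step per library, to within 0.001 of a read for 100% of the values, and the RPM scale divided by the step gave library totals of 78863514 to 80281076 reads. The lowest value in each library equalled 2 reads, so a circRNA with 1 read in a library is listed at 0. Reads worked out in this way describe depth and define the zeros of abundant circRNAs. They also enter the thinning, the checks of replicates and zeros, and the simulations. No count-based test of the group difference in circRNAs was run on them, because the deposited values begin at 2 reads. The planned count test was therefore left out. An entry of 0 is described as listed at 0.

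Host genes are not named in the table. They were assigned from GENCODE 29, on the same build and strand, first by exon boundaries at both ends, then at 1 end, then by the gene that contains the circRNA, with protein-coding genes preferred. A single host was found for 31563 circRNAs (95.6%), 925 had more than 1 candidate host and 528 had none. These last 2 sets entered no host or list test. Exon numbers refer to the GENCODE transcript chosen for each circRNA. A short-read junction shows only the 2 joined ends, so the inner exons are inferred from the annotation.

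The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(RPM + 0.0249), where the pseudocount is the smallest non-zero value of the table. CircRNAs above 0 in at least 3 of the 6 libraries were tested, which left 13152. All contrasts are no glucose minus high glucose, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates changes of low circRNAs. Values summed per host gene were tested in the same way. Switching between circRNAs of 1 host was tested with limma's diffSplice and the Simes method. Host gene lists with at least 5 tested circRNAs were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Values per library were compared by exact permutation tests, two-sided, for which 3 against 3 libraries give no p under 0.1. Tables were prepared in Python 3.11.15.

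The tests, the 17 gene lists, the rule for naming circRNAs and the alternatives were fixed before the data were examined, except 1 alternative and the tests named as such in the closing part. The naming rule took up to 10 circRNAs per direction that passed the threshold without overlap between groups, filled up to 5 per direction with the smallest unadjusted p. It added the 5 most abundant circRNAs, the most abundant and the smallest-p member of each list, the 3 host genes and 3 switching hosts with the smallest p, and the most abundant circRNA of HIPK3, ZKSCAN1, SMARCA5, FOXO3, ZNF609 and CDYL. The table used here has no row assigned to FOXO3. The design also named an overlap with a comparison by the authors, and the table analysed here holds none. Alternatives covered scaling, the limma settings, the filter, the pseudocount, a replicate block and each library left out.

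The junction reads behind the values numbered 123649 to 165883 per library, with a median of 4 or 5 reads per detected circRNA, so single circRNAs are measured with wide counting error. Replicates differed by more than counting error in each pair, and no library was a copy of another. The procedure was tested on simulated data for the comparison of no glucose with high glucose, with the means and library sizes of the real libraries, a replicate spread estimated from them and 200 changed circRNAs. The simulated data lack the zeros of abundant circRNAs, of which the real data held 186 and this spread predicts 0.127. The spread was estimated with the circRNAs that hold such zeros included. The shares called are therefore exact neither for the real data nor for data without such zeros. Among 13937 simulated circRNAs tested, 0% of changes of 2-fold were called. The share was 4.0% of changes of 4-fold among 13845 tested and 31.5% of changes of 8-fold among 13897 tested. When the changed circRNAs had at least 20 reads, 0% were called at 2-fold (13813 tested), 61.0% at 4-fold (13873 tested) and 85.5% at 8-fold (13790 tested). In 5 simulations without change of single circRNAs, which kept the group difference in summed circRNA, 0 circRNAs were called. Of 200 changed host genes, 38.0%, 82.0% and 98.0% were called at 2-fold, 4-fold and 8-fold, with 1, 2 and 2 unchanged host genes called. Of 200 switching hosts, 0%, 5.0% and 84.5% were called, with 0, 0 and 14 unchanged hosts called. Of the 14 lists, 13 were called by camera when all members changed 1.5-fold and 14 at 2-fold. Each circRNA was drawn independently, whereas the correlation estimated within the real lists reached 0.07, so the shares for lists may be too high. Changed host genes and lists were only raised, and switching was simulated as a rise of the host's most abundant circRNA.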

Results

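Circular RNAs are closed transcripts that form when a downstream splice site joins an upstream one. They were compared between MIA PaCa-2 pancreatic cancer cells kept for 3 h without glucose and cells kept in high-glucose medium, with 3 libraries per group. The question set by the series was which circRNAs differ in expression between the conditions. The libraries held 78863514 to 80281076 reads, of which 0.154% to 0.209% spanned a back-splice junction. The table listed 33016 circRNAs from 6211 assigned host genes. Of these, 14024 (42.5%) carried a circBase name, 14619 were above 0 in a single library and 4798 in all 6. Both ends lay at annotated exon boundaries for 28165 circRNAs.

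Summed circRNA was 1757 ± 295 RPM (SD, n = 3) in high glucose and 2015 ± 29.6 RPM (n = 3) without glucose, a difference of 14.7% (exact permutation test, two-sided, p = 0.4). The difference of 258 RPM was 426 RPM without high-glucose replicate 1 (exact permutation p = 0.1, the smallest these libraries can give) and 150 RPM without high-glucose replicate 3. The high-glucose libraries spread widely, at 2092.5, 1638.0 and 1540.2 RPM for replicates 1, 2 and 3, and the no-glucose libraries lay close together at 2045, 2014 and 1986 RPM. The number of circRNAs detected was 14250 ± 1904 in high glucose and 14669 ± 481 without glucose (n = 3 each, exact permutation p = 0.8), and this difference turned to 166 fewer without glucose once all libraries were thinned to 123649 junction reads. The difference in circRNAs detected, 419, was 1510 without high-glucose replicate 1, -8.83 without high-glucose replicate 2, -244 without high-glucose replicate 3, 632 without no-glucose replicate 1 and 158 without no-glucose replicate 2. The 100 most abundant circRNAs held 17.2% ± 0.188 and 17.3% ± 0.154 of the sum (n = 3 each, exact permutation p = 0.3).

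**Figure D1:**
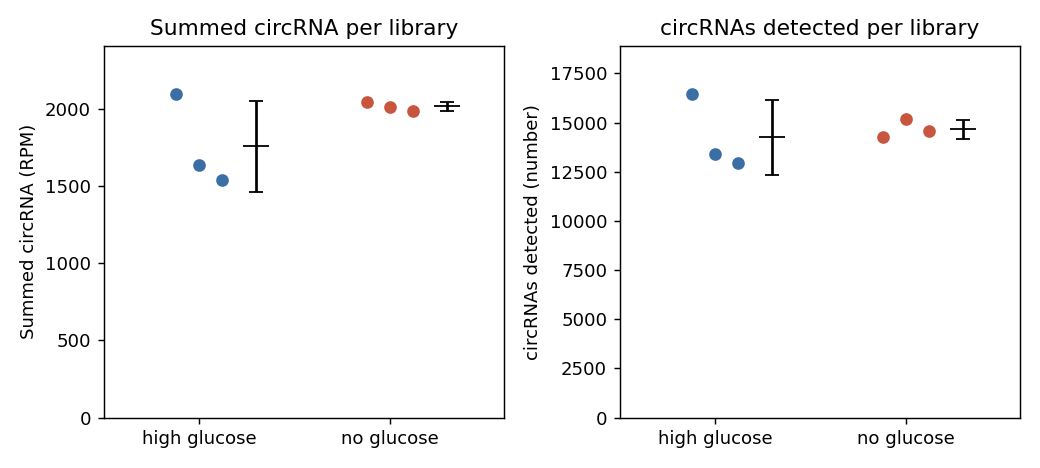
Summed circRNA in RPM (left axis panel) and the number of circRNAs detected (right axis panel) for the 3 high-glucose and 3 no-glucose libraries; each point is a library and the black marks are the mean ± SD. The high-glucose libraries run from 1540.2 to 2092.5 RPM and enclose the no-glucose libraries, at 1986 to 2045 RPM.

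Among the 5 most abundant circRNAs, those of ARHGAP12, HIPK3 and CDYL kept their order by group mean, while that of ASXL1 passed that of UBXN7. Each had a higher mean without glucose. The circRNA of exons 2 to 3 of ARHGAP12 (hsa_circ_0000231, chromosome 10, 31908172 to 31910563, minus strand, 5′ UTR and coding sequence), was highest at 22.98, 18.89 and 18.14 RPM in high glucose and 23.3 ± 0.781 RPM without glucose. The single-exon circRNA of exon 2 of the kinase gene HIPK3 (hsa_circ_0000284, chromosome 11, 33286413 to 33287511, plus strand) followed at 14.4 ± 2.47 and 15.8 ± 0.548 RPM. CDYL (hsa_circ_0008285, chromosome 6, 4891713 to 4892379, plus strand) gave 10.1 ± 1.67 and 11.4 ± 0.775 RPM, and UBXN7 (hsa_circ_0001380, chromosome 3, 196391813 to 196403019, minus strand) 8.20 ± 0.698 and 9.03 ± 0.541 RPM. ASXL1, a chromatin regulator (hsa_circ_0001136, exons 2 to 4, chromosome 20, 32366384 to 32369123, plus strand), stood at 7.94 ± 0.668 RPM in high glucose and 10.3 ± 0.892 RPM without glucose, with a log2 fold change of 0.37 (SE 0.15) that did not pass (limma, adjusted p = 0.915). Quantile normalization put ARHGAP12, HIPK3 and CDYL at a log2 fold change of 0, a value fixed by their top ranks in each library, and UBXN7 at -0.07. The widely studied circRNAs of ZKSCAN1 (hsa_circ_0001727), SMARCA5 (hsa_circ_0001445) and ZNF609 (hsa_circ_0000615) had log2 fold changes of 0.07, 0.13 and 0.14, all 3 below the median of all tested circRNAs, and with quantile normalization -0.08, -0.02 and -0.05.

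**Figure D2:**
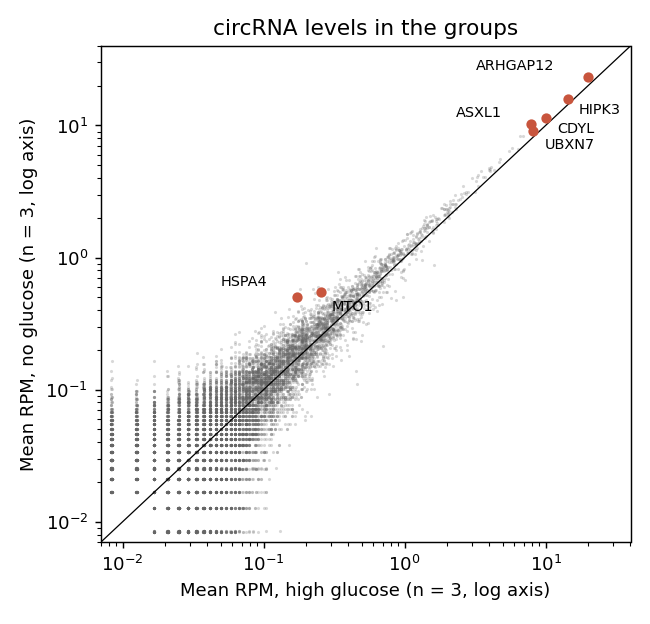
Mean RPM without glucose against mean RPM in high glucose (n = 3 per group, log axes) for each tested circRNA above 0 in both groups, with the line of equality; red points are named by host gene. The abundant circRNAs of ARHGAP12, HIPK3, CDYL, ASXL1 and UBXN7 lie close to the line, and those of HSPA4 and MTO1, which did not pass the adjusted threshold, lie above it.

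No circRNA changed at an adjusted p under 0.05 in the comparison of no glucose with high glucose. Of 13152 tested, limma called 0, and the smallest adjusted p was 0.915. At an unadjusted p under 0.05 there were 673, of which 470 were higher and 203 lower without glucose. Evenly spread p-values would give about 658, and other splits of the 6 libraries into 3 and 3 gave 559 to 837. The 673 therefore lay near the number for evenly spread p-values and within the range of other splits. The 5 simulations without change of single circRNAs gave 768 to 818. They kept the junction reads of each library, and so the group difference in summed circRNA, and are no benchmark free of a group shift. Fold changes leaned upward: 59.4% were positive and the median log2 fold change was 0.15. Median-centring brought that median to 0.01 and the unadjusted split to 320 higher and 336 lower, and quantile normalization brought the split to 333 and 303. Without high-glucose replicate 1 the split was 801 higher and 147 lower, and among circRNAs above 0 in all 6 libraries it was 261 and 32. The median log2 fold change was 0.22 without high-glucose replicate 1, 0.10 without high-glucose replicate 2 and 0.07 without high-glucose replicate 3, with 63.1%, 56.3% and 54.3% of fold changes positive. Other settings called 0 to 49 circRNAs. The 49 arose with no filter, and 46 of them were abundant circRNAs listed at 0 in 1 or more libraries. With no filter, other splits of the 6 libraries into 3 and 3 called 33 to 60.

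Among circRNAs higher without glucose, none of which passed, the smallest unadjusted p belonged to exons 2 to 4 of HSPA4, a member of the HSP70 chaperone family. This circRNA (circRNA_11081, chromosome 5, 133064980 to 133070496, plus strand, coding) measured 0.171 ± 0.0643 RPM in high glucose and 0.506 ± 0.0446 RPM without glucose (n = 3 each), a log2 fold change of 1.49 (SE 0.33). Its groups did not overlap, as for 1520 of the 13152 circRNAs tested. Other splits of the 6 libraries into 3 and 3 gave 1091 to 1539 such circRNAs. The HSPA4 circRNA passed when only circRNAs above 0 in all 6 libraries were tested (limma, adjusted p = 0.0431), and over the other settings its adjusted p ran up to 0.979. Among circRNAs above 0 in all 6 libraries the real split called 2, and the highest other split called 2 as well. Exons 8 to 9 of MTO1, a mitochondrial tRNA modification gene (hsa_circ_0004973, chromosome 6, 73480675 to 73482244, plus strand), measured 0.255 ± 0.0333 and 0.544 ± 0.0459 RPM, a log2 fold change of 1.03 (SE 0.28). Exons 3 to 5 of CNTLN (circRNA_16579, chromosome 9, 17226203 to 17236588) were listed at 0.0252, 0 and 0 RPM in high glucose and at 0.165, 0.177 and 0.152 RPM without it. USP32 (hsa_circ_0000793), from a deubiquitinase gene, was listed at 0, 0.0498 and 0 RPM against 0.215, 0.126 and 0.152 RPM. UXS1, which encodes UDP-glucuronate decarboxylase (hsa_circ_0001060, chromosome 2, 106158058 to 106166083), was listed at 0, 0.598 and 0 RPM against 0.722, 0.973 and 1.01 RPM. It was called without high-glucose replicate 2 (adjusted p = 0.00161), the library of that group that detected it, with a 10 times larger pseudocount (adjusted p = 0.0342) and with no filter (adjusted p = 1.62e-13), and its adjusted p ran up to 0.963 elsewhere. CNTLN circRNA_16579 was called with no filter alone (limma, adjusted p = 0.0398, up to 0.991 elsewhere).

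Among circRNAs lower without glucose, again none passed. The circRNA of exons 17 to 21 of PTK2, the focal adhesion kinase gene (hsa_circ_0003171, chromosome 8, 140739018 to 140752316, minus strand), was listed at 0.429, 0.561 and 0.386 RPM in high glucose and at 0.329, 0 and 0 RPM without glucose. APLP2 (hsa_circ_0000372, chromosome 11, 130109429 to 130110661) was listed at 0.946, 0.548 and 0.598 RPM against 0, 0 and 0.647 RPM, and it was called without no-glucose replicate 3 (limma, adjusted p = 0.0252) and with no filter (adjusted p = 4.11e-09). Exons 7 to 14 of the splicing factor gene RBM39 (hsa_circ_0004193) gave 0.0631, 0.0748 and 0.112 RPM (5, 6 and 9 reads) in high glucose and were listed at 0 in each no-glucose library. So was COL4A3BP (circRNA_10543), with 0.114, 0.0374 and 0.125 RPM (9, 3 and 10 reads) in high glucose. ZNF800 (hsa_circ_0082096) was listed at 0.429, 0.424 and 0.511 RPM against 0.203, 0.215 and 0 RPM. With no filter, PTK2 hsa_circ_0003171 (limma, adjusted p = 6.20e-06) and ZNF800 (adjusted p = 0.00239) were called too, and in other settings the adjusted p of PTK2, APLP2 and ZNF800 ran up to 0.979.

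Host genes of glucose metabolism did not stand apart. Of 40 tested circRNAs from 16 genes of glucose transport and glycolysis, 22 were higher and 18 lower without glucose, with a median log2 fold change of 0.10, which is -0.04 from the median of all circRNAs. The most abundant was from UGP2, which makes UDP-glucose (hsa_circ_0001020), at 0.747 ± 0.108 and 0.620 ± 0.111 RPM. The smallest p was for PFKFB3, a regulator of glycolytic flux (hsa_circ_0017608), at 0.0378, 0.0374 and 0.0249 RPM in high glucose and listed at 0 in all 3 no-glucose libraries. These PFKFB3 values stand for 3, 3 and 2 reads, and 2 reads is the lowest value listed. In all, 288 circRNAs were above 0 in all 3 libraries of 1 group and in none of the other. Other splits of the 6 libraries into 3 and 3 gave 301 to 362 such circRNAs. Mitochondrial metabolism had 60 higher and 24 lower of 84 circRNAs, with a median of 0.29, or 0.14 above that of all circRNAs (camera, adjusted p = 0.902). Within it OGDH, of the citric acid cycle (hsa_circ_0003340), measured 0.722 ± 0.172 and 0.975 ± 0.284 RPM. Citrate synthase, CS (hsa_circ_0026978), gave 0.0378, 0.0748 and 0.0747 RPM (3, 6 and 6 reads) in high glucose and was listed at 0 without it.

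Hosts of stress and nutrient-sensing genes were likewise spread on both sides, as were all tested circRNAs, of which 59.4% were higher without glucose. The unfolded protein response list had 41 higher and 25 lower of 66 circRNAs. Its most abundant member, UGGT1 (hsa_circ_0008298), measured 0.530 ± 0.138 and 0.519 ± 0.158 RPM, and SEC31A, of the COPII vesicle coat (hsa_circ_0003549), 0.0875 ± 0.0327 and 0.279 ± 0.0773 RPM without overlap between groups. The integrated stress and amino acid list had 41 higher and 32 lower of 73, with a median log2 fold change of 0.04, or -0.09 after median-centring. Among its members, the isoleucyl-tRNA synthetase IARS (hsa_circ_0006702) measured 1.38 ± 0.0811 and 1.89 ± 0.215 RPM. The kinase gene EIF2AK2 (circRNA_03908) was listed at 0 in high glucose and at 0.0506, 0.0505 and 0.0380 RPM (4, 4 and 3 reads) without it. In the AMPK, mTOR and autophagy list 66 of 107 were higher and 41 lower. AMBRA1 (hsa_circ_0007001) gave 0.933, 0.984 and 0.922 RPM in high glucose and 0.937, 1.19 and 0 RPM without. PIK3R4 (circRNA_07675) had 5, 2 and 5 reads in high glucose and was listed at 0 in the no-glucose libraries. The RAS, MAPK and PI3K list had 115 higher and 71 lower of 186, led by another PTK2 circRNA (hsa_circ_0002483) at 1.84 ± 0.354 and 2.36 ± 0.238 RPM.

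Hosts of nuclear and structural genes gave the same picture. RNA-binding and circRNA biogenesis factors had 76 higher and 49 lower of 125, with RBM39 (hsa_circ_0004870) most abundant at 1.70 ± 0.405 and 1.82 ± 0.0953 RPM, a log2 fold change of 0.12 that was -0.02 after median-centring and -0.11 with quantile normalization. Chromatin regulators had 213 higher and 161 lower of 374, and EP300 (circRNA_32191) had the smallest p, at 0, 0.0498 and 0.0996 RPM against 0.215, 0.164 and 0.228 RPM. Cell cycle and DNA repair had 176 higher and 142 lower of 318, with FANCL (hsa_circ_0001009) at 2.79 ± 0.991 and 3.11 ± 0.320 RPM and the Mediator kinase CDK8 (hsa_circ_0029803) at 0.342 ± 0.0878 and 0.633 ± 0.0375 RPM. Ubiquitin ligases and deubiquitinases had 286 higher and 170 lower of 456, with FBXW7 (hsa_circ_0001451) at 2.06 ± 0.345 and 2.27 ± 0.3996 RPM, which quantile normalization turned to a log2 fold change of -0.06. Adhesion, cytoskeleton and matrix genes had 159 higher and 102 lower of 261, with SMAD4 (circRNA_29315) at 0, 0.0623 and 0.0498 RPM against 0.228, 0.177 and 0.127 RPM. Hosts of widely described circRNAs had 242 higher and 123 lower of 365. Nuclear transport had 137 higher and 96 lower of 233, with XPO1 (hsa_circ_0001017) at 7.92 ± 1.30 and 9.02 ± 0.0379 RPM, turned to a log2 fold change of -0.07 by quantile normalization, and XPO6 (hsa_circ_0038773) at 0.150 ± 0.0260 and 0.354 ± 0.0707 RPM.

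None of the 14 lists with enough circRNAs passed a test. Against the other circRNAs, the smallest adjusted p was 0.902 with camera and 0.981 with camera and an estimated correlation. Against no change, which is what fry tests, it was 0.514 in 1 direction and 0.168 in either direction. In every list 0 circRNAs passed over all tested, and 0 passed adjusted over the list alone. The lowest p adjusted over the list alone was 0.0991, in the list of nuclear and precursor RNAs. That list had 10 higher and 6 lower of 16, with NEAT1 (hsa_circ_0003812) at 0.0757, 0 and 0.0249 RPM against 0.203, 0.0884 and 0.279 RPM, and MALAT1 (hsa_circ_0004106) at 0.202, 0.125 and 0.0996 RPM against 0.241, 0 and 0.178 RPM. Markers of other cell types were nearly missing from the table. The blood and endothelial list had 1 circRNA, from ITGAM, above 0 in a single library, the fibroblast and stellate list had 2, with COL6A3 above 0 in a single library, and the acinar, islet and liver list had 0.

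**Figure D3:**
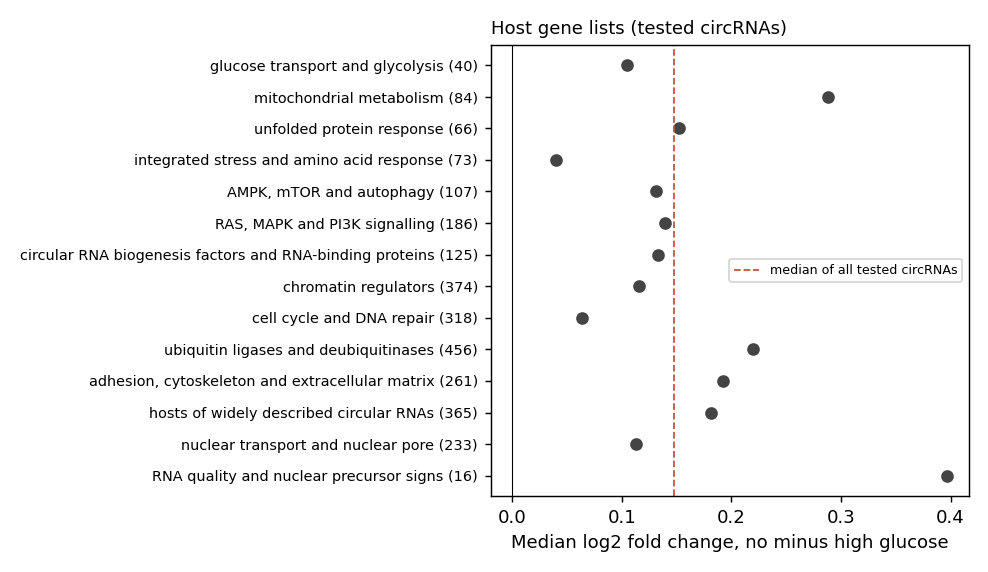
Median log2 fold change (no glucose minus high glucose, horizontal axis) of the tested circRNAs of each host gene list, with the number of circRNAs in parentheses; the dashed line is the median of all 13152 tested circRNAs, 0.15. The lists lie on both sides of that line and none passed camera, which compares each list with the other circRNAs.

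Summed per host gene, no circRNA output passed the threshold. Of 4504 host genes limma called 0, with 265 at an unadjusted p under 0.05 and a smallest adjusted p of 0.838. Other splits of the 6 libraries into 3 and 3 gave 140 to 381 host genes at an unadjusted p under 0.05. The 265 became 540 without high-glucose replicate 1, 154 without high-glucose replicate 2 and 175 without high-glucose replicate 3, where the smallest adjusted p was 0.263, 0.991 and 0.975. CNTLN had the smallest p, with 0.159 ± 0.0200 RPM over its 8 circRNAs in high glucose and 0.494 ± 0.0763 RPM without glucose, a log2 fold change of 1.49 (SE 0.34). STARD3NL followed at 0, 0.0249 and 0 RPM against 0.152, 0.190 and 0.127 RPM. FRG1HP, a pseudogene of a family with near-identical copies, whose reads are therefore uncertain, was listed at 0 in high glucose and at 0.101, 0.0884 and 0.114 RPM without it.

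One host gene, PTK2, passed the test for switching between its circRNAs. Of 2419 host genes with at least 2 tested circRNAs, limma's diffSplice called 1, PTK2, with 34 circRNAs (Simes adjusted p = 0.00403). Other splits of the 6 libraries into 3 and 3 called up to 2 host genes. Its hsa_circ_0003171 was the member listed at 0 in no-glucose replicates 2 and 3, with 26 reads in replicate 1. Of 1336 abundant circRNAs, 166 were listed at 0 in at least 1 library. Of the 166, 148 were at 0 in exactly 1 library, so zeros in 2 libraries, as here, were less common. PTK2 hsa_circ_0002483 was at 2.25, 1.63 and 1.63 RPM in high glucose and 2.22, 2.24 and 2.64 RPM without it. UXS1 (adjusted p = 0.223) and RHEB, a GTPase upstream of mTOR (adjusted p = 0.748), followed and did not pass. The PTK2 call was lost when circRNAs had to be above 0 in all 6 libraries, which leaves out hsa_circ_0003171 among other PTK2 members. It was also lost without high-glucose replicate 2, where UXS1 was called in its place. The same held without no-glucose replicate 2, with WDR7 and DHX34 called, and without no-glucose replicate 3, with APLP2 called.

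The classes given in the table were compared by their share of the summed RPM. Both ends lay at annotated exon boundaries for 26459 of 29999 sense-overlapping circRNAs and 431 of 1257 intergenic ones. Of the 1344 exonic ones, 1161 spanned 1 annotated exon. The exonic class is therefore not the whole of the circRNAs bounded by exons. Sense-overlapping circRNAs made up 88.0% ± 0.306 of the sum in high glucose and 87.9% ± 0.0547 without glucose, exonic ones 9.09% ± 0.309 and 9.08% ± 0.118, and intergenic ones 2.43% ± 0.0359 and 2.54% ± 0.0830 (n = 3 each). CircRNAs without a circBase name held 21.1% ± 0.556 and 21.1% ± 0.215. The intergenic share was 2.47%, 2.40% and 2.43% in the high-glucose libraries and 2.62%, 2.46% and 2.53% in the no-glucose libraries. With 3 libraries per group no class could pass an exact permutation test after adjustment, so these tests do not tell whether the shares differ.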

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

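The alternative that left out circRNAs listed at 0 against 20 or more reads elsewhere was chosen after seeing the data. Of the values that answer a comparison, 117 kept their side of the threshold and their size or direction, 18 moved and 14 turned in direction. Of those for named genes, 694 kept both, 13 came to pass the threshold, 5 ceased to pass and 19 turned or fell to a log2 fold change of 0. Where a value changed, the cause was not tested unless it is named. CircRNAs called, 0 in the main test, numbered 2 with robust limma (MAGI1 higher, SPIDR lower) and 49 with no filter (24 higher, 25 lower). They numbered 2 when above 0 in all 6 libraries (HSPA4 higher, ARHGAP5 lower), 1 with 10 times the pseudocount (UXS1) and 0 at an adjusted p under 0.1. Other splits of the 6 libraries into 3 and 3 called 0 to 11 with robust limma and 33 to 60 with no filter. The same splits called 0 to 2 when above 0 in all 6 libraries and 0 to 2 with 10 times the pseudocount. Leaving out 1 library gave 0 to 1 called circRNAs, namely UXS1 without high-glucose replicate 2, WDR7 without no-glucose replicate 2 and APLP2 without no-glucose replicate 3. A looser cut, an unadjusted p under 0.05 and 2-fold, gave 581 (384 higher, 197 lower), and other splits gave 532 to 704. Host genes called, 0 in the main test, numbered 1 with robust limma and 4 with no filter. Switching hosts, 1 in the main test, numbered 3 with no filter, 0 when above 0 in all 6 libraries, 2 with 10 times the pseudocount and 1 to 2 with 1 library left out. They numbered 0 without circRNAs at 0 against 20 reads, which leaves out hsa_circ_0003171 and hsa_circ_0007786 of PTK2. List calls stayed at 0 in each setting run. The limma settings do not enter the list and switching tests.

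The share of positive fold changes, 59.4%, was 50.8% with quantile normalization, 51.0% after median-centring and 68.5% when above 0 in all 6 libraries. Quantile normalization put the log2 fold change at 0 for ARHGAP12, HIPK3 and CDYL, because they hold the top ranks of each library, and at -0.0658 for UBXN7, -0.11 for RBM39 (hsa_circ_0004870), -0.0623 for FBXW7, -0.0658 for XPO1, -0.0815 for ZKSCAN1, -0.0213 for SMARCA5 and -0.0522 for ZNF609. Median-centring gave -0.0168 for RBM39, -0.0674 for ZKSCAN1 and -0.0039 for SMARCA5. With 1 library left out, log2 fold changes ran from -0.24 to 0.20 for UGGT1, -2.65 to 0.15 for AMBRA1, -1.19 to 0.52 for MALAT1, -0.0076 to 0.16 for ZKSCAN1 and -0.0333 to 0.30 for SMARCA5.

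The difference in circRNAs detected was -166 after thinning and ran from -244 to 1510 with 1 library left out. The difference in the share of the most abundant circRNAs was -0.0928 percentage points for the 1000 most abundant. Differences in class shares, in percentage points, ran from -0.0105 to 0.0084 for antisense, -0.152 to 0.155 for exonic, -0.0371 to 0.0055 for intronic, -0.262 to 0.0258 for sense-overlapping and -0.174 to 0.324 for circRNAs without a circBase name, with 1 library left out. Over tested circRNAs alone the last was -0.166.

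With the replicate number as a block (replicate block), 0 circRNAs, 0 host genes and 0 lists were called and 1 switching host, PTK2 (adjusted p = 0.0151). Deviations of same-numbered libraries correlated at 0.0134, -0.0074 and 0.0069, which gives no sign of pairing. Single circRNAs carry wide counting error that can hide a shared experiment, so pairing by number is not excluded. The planned count test was not run. In the simulation, 4-fold changes were called for 4.0% of all tested circRNAs and 61.0% of those with 20 or more reads, and 2-fold changes for 0% of both. In these simulated data few reads limit calls at 4-fold, and what limits them at 2-fold was not tested.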

Other observations

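The tests of counting noise, nearby junctions, glucose, the spread of sums, the calls with no filter, PTK2 and other splits were chosen after their results were seen. The test of circRNAs sharing an end and that of chaperone hosts were written down first, though the chaperone list was drawn up after HSPA4 had been seen and its tests with all circRNAs kept and on HSPA4 alone were added later.

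CircRNAs that begin at exon 2 of their transcript held 38.1% ± 0.207 of the RPM in high glucose and 38.0% ± 0.369 without glucose (n = 3 each, exact permutation p = 0.7), although they were 25.3% of the 26857 circRNAs with exons assigned. Those spanning 2 exons held 30.6% ± 0.633 and 31.1% ± 0.329 (exact permutation p = 0.3), and single-exon ones 9.49% ± 0.276 and 9.48% ± 0.0980 (exact permutation p = 0.9). CircRNAs spanning 5′ UTR and coding sequence held 18.7% ± 0.0194 and 18.6% ± 0.0228 (exact permutation p = 0.1, the smallest these libraries can give), with no overlap between the groups. Adjusted over the structure measures compared, this exact permutation p was 0.9. The median exonic length weighted by RPM was 416 bases in high glucose and 414 without glucose. By host gene, ARHGAP12 gave the most circular RNA (21.8 ± 2.85 and 25.4 ± 0.632 RPM over 26 circRNAs), followed by XPO1 (15.4 ± 2.23 and 17.7 ± 0.592 RPM over 55). BIRC6, which encodes a large ubiquitin-conjugating enzyme, had the most circRNAs, 73, at 3.72 ± 0.437 and 4.63 ± 0.440 RPM in sum.

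Abundant circRNAs were listed at 0 in single libraries. Of 1336 circRNAs above 0 in at least 3 libraries and with a mean of 20 or more reads where detected, 166 (12.4%) were listed at 0 somewhere, 148 of them in exactly 1 library. AMBRA1 hsa_circ_0007001, for example, had 74, 79, 74, 74 and 94 reads in 5 libraries and 0 in no-glucose replicate 3, the library that held 74 of the 186 zeros. Counting predicts 0.000155 such zeros, or 0.127 with the spread between replicates. Reads at a junction within 20 bases were present for 6 zeros, and circRNAs sharing an end gained a median of -0.0054 of the missing reads. Of the affected circRNAs, 0 were listed at 0 in all 3 libraries of 1 group only, so none was lost from a whole group. A partial effect of glucose need not give that pattern and is not excluded. The zeros numbered 23, 18 and 24 in high-glucose replicates 1, 2 and 3 and 26, 21 and 74 in the no-glucose replicates. The authors' detection or filtering in each library stays open as a candidate cause and was not tested.

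Of the 49 circRNAs called with no filter, 46 had such a zero, as did the PTK2 member hsa_circ_0003171, with 34, 45, 31 and 26 reads where detected. Leaving out circRNAs with zeros of abundant circRNAs gave 0 calls with no filter and 0 calls of PTK2. For the 46 that removes the called circRNAs themselves, and for PTK2 it removes hsa_circ_0003171 and hsa_circ_0007786. It therefore does not tell whether the zeros are the reason for the calls. The other circRNAs called with no filter, of MAGI1 (circRNA_07249), ARHGAP5 (hsa_circ_0031583) and CNTLN (circRNA_16579), stayed in the test and were no longer called.

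The high-glucose libraries differed from each other in summed circular RNA by 35.9%. Their total reads differed by 1.27%, so the denominator does not account for this. Without the 100 most abundant circRNAs the sums still differed by 36.5%. The median log2 ratio of 1170 abundant circRNAs lay within 0.0270 of the log2 ratio of the sums for each pair, which is consistent with a factor common to most circRNAs. Whether that factor lies in the culture, in RNA quality or in library preparation stays open, and no biological explanation was tested.

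HSPA4 prompted the hypothesis that circRNAs of chaperone hosts are higher without glucose. Without circRNAs that had such zeros, over 106 circRNAs of 29 chaperone hosts, 64 were higher and 42 lower, and the median log2 fold change, 0.12, lay below that of all circRNAs, 0.15 (limma's fry 0.294 and camera 0.993, unadjusted). That left out HSPA4 hsa_circ_0001531 (0, 29 and 27 reads in high glucose, 48, 49 and 31 without glucose), which was called with no filter. With all 111 circRNAs of 30 hosts kept, 66 were higher and 45 lower with a median of 0.12 (fry 0.320, camera 0.974, unadjusted). HSPA4 circRNA_11088 had 0, 4 and 0 reads in high glucose and 8, 6 and 5 without glucose. Adjusted over the shorter list alone HSPA4 circRNA_11081 passed (limma, adjusted p = 0.00833), but HSPA4 is the reason the list exists, so this is no separate evidence. The outcome set in advance against the hypothesis, a fry value above 0.05, was met by both lists. The 11 circRNAs of HSPA4 alone, 6 higher and 5 lower, would meet it as well (fry 0.0638, unadjusted), so this bound was too weak to decide and the hypothesis stays open without support from the other hosts.

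The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In the main test all 10 splits gave 0 circRNAs, 0 host genes and 0 lists called. The real split gave 1 switching host and the highest other 2, with 4 of the 10 splits, the real one included, giving at least 1. At an unadjusted p under 0.05 the real split gave 673 circRNAs and the highest other 837, with 4 of the 10 splits, the real one included, giving at least 673. The real split had 288 circRNAs detected in all 3 libraries of 1 group and in none of the other, 163 in no glucose and 125 in high glucose, and the highest other split had 362, with all 10 splits, the real one included, at or above 288. Among the 163 were ING5 (hsa_circ_0059116) and DROSHA (hsa_circ_0072046), each with 24 reads in total, named here after their values were seen.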
